A study of Rattus norvegicus with 8 samples.

How the data were processed

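RNA was isolated with the Arcturus PicoPure kit and samples with a RIN above 8 were used for polyA-enriched libraries, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, MultiQC 1.12, fastp 0.23.2, Trimmomatic, kallisto 0.48.0, featureCounts, DESeq2 1.40.2 and the genome build rn6, without the role or order of each tool. The deposited table holds estimated counts per gene for each of the 8 libraries, not normalized. Between 32.5% and 33.6% of the values in a library differed from a whole number by more than 1e-06, so the values were rounded to whole numbers before any test. The strand setting and the handling of reads that match several genes are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain. Each library column was tied to its sample by its name in the labels.

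Groups were taken from the sample titles, 4 control and 4 doxorubicin rats. Of 2356 rows without a symbol, 7 were named through their Entrez identifier from a RefSeq gene table of the GRCr8 assembly, which was used for names only. No coordinates are printed, since no annotation of the files' build was at hand, and the planned test of gene length against fold change was therefore not run. Every pair of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of at least 6.22 over genes with 20 or more counts, so all 8 were counted as separate samples.

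Tests were run in R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1. Genes were kept by filterByExpr, scaled by TMM, and tested with edgeR's quasi-likelihood F test (estimateDisp, glmQLFit with robust = TRUE, glmQLFTest) with no covariate. Benjamini-Hochberg adjustment ran over the 16976 genes kept, with a threshold of 0.05 and no minimum fold change. The common biological coefficient of variation was 8.82%. CPM (counts-per-million) values are TMM-scaled, and errors are SD over 4 rats for CPM and SE for log2 fold changes. Standard errors were taken from the size of the log2 fold change and its F value, and intervals cover 95%.

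A fixed set of 39 gene lists, written before the data were examined, was tested with limma's camera on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and at least 5 members per list. Adjustment ran over the 39 lists, and 17 list members were matched through other symbols. Camera with an estimated correlation and fry were alternatives. Library measures and list means were compared by two-sided exact permutation tests over the 70 arrangements of 8 libraries, whose smallest p is 0.0286.

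The genes to name were set by a rule made before the data were examined. Among genes past the threshold with a symbol of their own, at least 1 CPM in a group and no overlap between groups, it took the 8 with the largest log2 fold change and the 4 with the smallest p in each direction. It also took up to 4 members past the threshold from each list, and 15 genes whatever their result (Cdkn1a, Mdm2, Bax, Bbc3, Pmaip1, Fas, Top2a, Top2b, Kit, Gfra1, Zbtb16, Id4, Ddx4 and Dazl, with 1 more that is not reported here), 26 genes in all. A further 18 genes were chosen after their values were seen: the other genes past the threshold, up to 4 members with the smallest p adjusted over the list alone from each list called by camera and from the erythroid list, and Abcb1a as the paralog of Abcb1b.

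The procedure was tested on simulated data with the means and library sizes of these samples. For doxorubicin against control over 16976 simulated genes, 82% of 50 genes changed 1.5-fold and 98% of 50 genes changed 2-fold were called, and 11 of 182 calls were false. The simulated counts were drawn independently for each gene, with no rat that responded more strongly and no structure among the rats. These shares therefore need not hold for the real data. Alternatives were DESeq2, limma-voom, RLE factors, library size only, no filter or a mean of at least 1 CPM, a fit that was not robust, thinning to the smallest library, other thresholds, and leaving out each library in turn. Other fits were added after seeing the data, among them blocks for 2 splits of the animals.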

Results

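Transcript abundance was measured by polyA-enriched RNA sequencing in GFP-positive germ cells isolated from the testes of prepubertal transgenic Sprague-Dawley rats that carry the GCS-EGFP germ cell reporter. The rats had received doxorubicin at 5 mg/kg or vehicle on postnatal day 6, and the cells were collected 24 h later. Doxorubicin is an anthracycline chemotherapy drug that traps topoisomerase II on DNA and causes strand breaks. Libraries came from 4 control rats (numbers 1, 4, 5 and 9) and 4 doxorubicin rats (numbers 2, 3, 6 and 8), each a separate animal. Total estimated counts per library ran from 41253800 in control rat 9 to 58871000 in doxorubicin rat 2. In the smallest library, an abundance of 1 CPM (counts-per-million) corresponded to 41.3 counts, which gives a counting error of 15.6%. Of 24059 genes in the table, 16976 were tested.

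The comparison of doxorubicin with vehicle asks how the drug changed germ cell transcripts within a day of exposure. Over all genes, edgeR called 3 p53 target genes, all higher after doxorubicin. Eda2r (ENSRNOG00000013018.9), a receptor of the TNF receptor family, rose from 1.83 ± 0.27 CPM in controls to 11.8 ± 2.96 CPM after doxorubicin (SD, n = 4 each), a log2 fold change of 2.68 ± 0.18 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.63e-05). Ccng1 (ENSRNOG00000003256.8), which encodes cyclin G1, rose from 22.3 ± 1.82 to 134.9 ± 52.3 CPM, a log2 fold change of 2.59 ± 0.27 (edgeR adjusted p = 0.0411). Aen (ENSRNOG00000018421.7), an apoptosis-enhancing nuclease, rose from 46.1 ± 1.62 to 95.2 ± 19.8 CPM, a log2 fold change of 1.05 ± 0.13 (edgeR adjusted p = 0.0411). For each of these 3 genes all doxorubicin libraries lay above all control libraries.

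Across the p53 target list as a whole, 49 of 62 measured members had a positive log2 fold change, with a median of 0.22. Over all genes tested, 3 members passed the edgeR threshold and 25 that of DESeq2, all higher. Adjusted over the list alone, 30 members passed, all of them higher, and 29 members had no overlap between the groups, where chance gives 2.86% of genes in both directions together. Several of the best known targets did not pass edgeR over all genes but did when adjusted over the list alone, which for Bbc3, Fas, Cdkn1a, Bax and Mdm2 gave edgeR adjusted p = 0.00112, 0.00112, 0.00158, 0.00464 and 0.0182 in the p53 target list. Bbc3, which encodes the pro-death protein PUMA, measured 1.29 ± 0.58 CPM in controls and 11.2 ± 5.47 CPM after doxorubicin, a log2 fold change of 3.10 ± 0.42 (edgeR adjusted p over all genes = 0.0726). The death receptor Fas had a log2 fold change of 2.50 ± 0.43 (edgeR adjusted p over all genes = 0.0801), and Cdkn1a, the cell cycle inhibitor p21, had one of 1.86 ± 0.31 (edgeR adjusted p over all genes = 0.107). Over all genes, DESeq2 called Bbc3, Fas, Cdkn1a and Bax (adjusted p = 4.41e-09, 2.67e-08, 6.44e-06 and 0.00372) but not Mdm2 (adjusted p = 0.0773). Bbc3, Fas and Cdkn1a also passed edgeR over all genes without robust fitting and without doxorubicin rat 2. Bax stood at 57.1 ± 5.43 CPM in controls and 75.5 ± 10.1 CPM after doxorubicin, and Mdm2, a ubiquitin ligase, at 152.9 ± 10.5 and 185.6 ± 23.6 CPM. Pmaip1, which encodes NOXA, had a log2 fold change of 0.56 ± 0.21 and did not pass over all genes (edgeR adjusted p = 0.651; DESeq2 adjusted p = 0.417).

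The p53 target list rose as a set in camera with a preset correlation of 0.01 (adjusted p over 39 lists = 6.66e-22). With an estimated correlation its p was 0.0211 and its adjusted p = 0.411, and fry gave adjusted p = 0.0536. The list mean had an exact permutation p of 0.0286, the smallest that the design can give (0.223 adjusted over 39 lists). The list of pro-death Bcl2 family members and death receptors, of which 6 members are also p53 targets, rose as well (camera adjusted p = 0.00807; adjusted p = 0.624 with an estimated correlation), with 14 members positive and 6 negative and a median log2 fold change of 0.07. Of its 20 members, 5 passed when adjusted over the list alone, all higher: Eda2r, Bbc3, Fas, Bax and Bcl2l11. Over all genes, 1 passed edgeR and 4 passed DESeq2, all higher. Other lists of apoptosis did not pass. Of the 20 caspases and effectors, 11 were positive and 9 negative (camera adjusted p = 0.527), with 0 past the threshold over all genes (2 higher at an unadjusted p below 0.05, and 1 higher with DESeq2) and 1 higher when adjusted over the list alone. Of the 15 survival factors, 6 were positive and 9 negative (camera adjusted p = 0.628), with 0 past it over all genes or over the list alone (1 higher and 2 lower at an unadjusted p below 0.05, and 0 with DESeq2). Doxorubicin rat 2 stood apart in both lists, with a mean log2 CPM of 4.57 for the p53 targets, against 4.15 to 4.19 in the other treated rats, and of 3.74 for the pro-death list, against 3.38 to 3.40. Both list calls held when any one of the 8 libraries was left out.

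**Figure D1:**
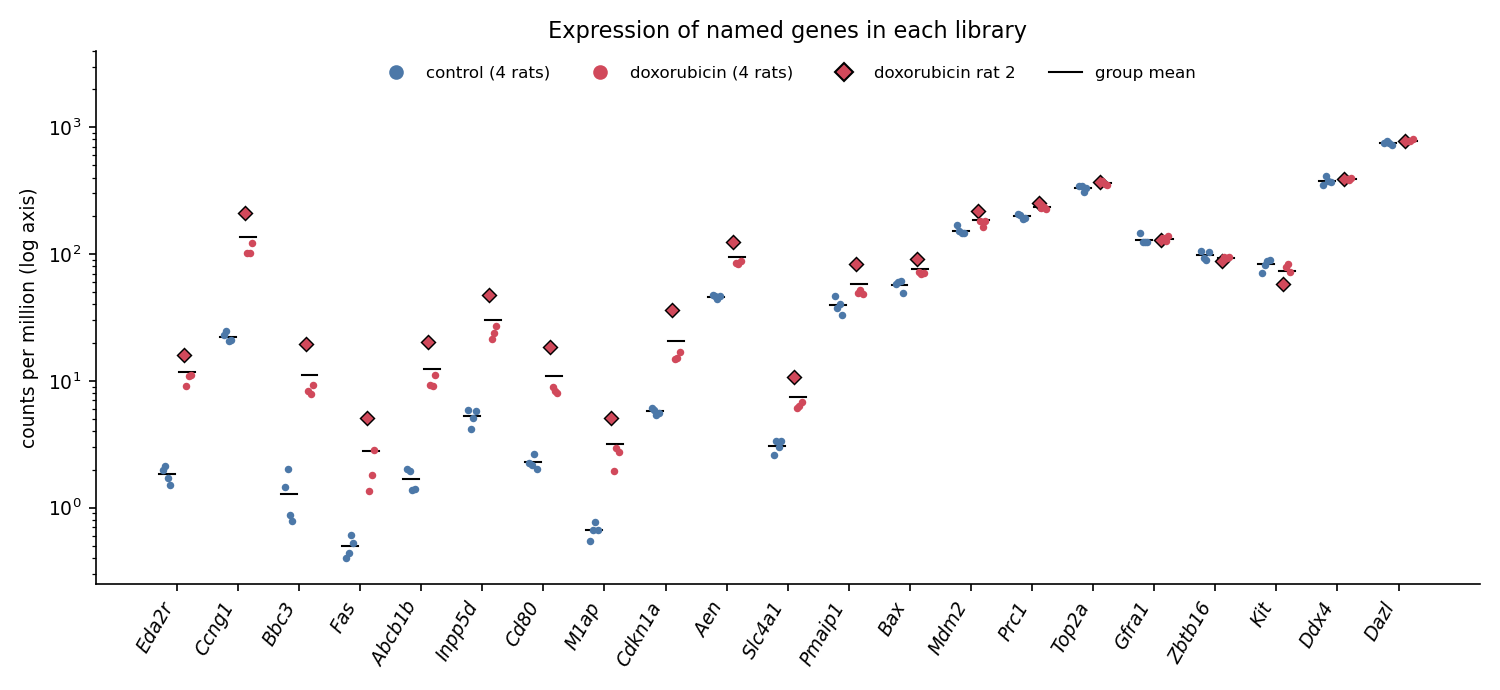
Expression of 21 named genes in each library, in CPM on a log axis, with 1 point per rat (4 control in blue, 4 doxorubicin in red) and a bar at each group mean. Doxorubicin rat 2, drawn as a diamond, is the highest treated library for Eda2r, Ccng1, Bbc3, Fas and Cdkn1a, and the germ cell genes on the right overlap between the groups.

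Genes outside these lists changed as well. Abcb1b (ENSRNOG00000066042.1), a P-glycoprotein efflux pump, rose from 1.69 ± 0.33 to 12.4 ± 5.28 CPM, a log2 fold change of 2.87 ± 0.30 (edgeR adjusted p = 0.018). Its close paralog Abcb1a had a log2 fold change of 0.19 ± 0.32 (adjusted p = 0.968) at 0.444 ± 0.148 CPM in controls, and how reads were divided between the pair is uncertain. Inpp5d, the lipid phosphatase SHIP1, rose with a log2 fold change of 2.52 ± 0.28, and Cd80, a costimulatory ligand, with one of 2.27 ± 0.30 (edgeR adjusted p = 0.0411 for both). M1ap, a meiosis gene, rose from 0.667 ± 0.095 to 3.18 ± 1.33 CPM (log2 fold change 2.26 ± 0.28, edgeR adjusted p = 0.018). Rnf169, a ubiquitin-binding protein of the DNA double-strand break response, and Ddias, an apoptosis suppressor induced by DNA damage, rose with log2 fold changes of 0.68 ± 0.08 and 0.44 ± 0.05 (edgeR adjusted p = 0.0162 for both). Slc4a1, the band 3 anion exchanger of red cells, rose from 3.09 ± 0.35 to 7.48 ± 2.21 CPM (edgeR adjusted p = 0.0339). The globin genes Hbb and Hba-a1, from the same erythroid list, had log2 fold changes of -1.17 ± 0.29 and -0.88 ± 0.22. They did not pass edgeR over all genes (adjusted p = 0.192 and 0.206), but did with DESeq2 (adjusted p = 0.0243 and 0.0382) and with edgeR when adjusted over the list alone (adjusted p = 0.00495 for both).

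In total 18 genes were higher and 1 was lower after doxorubicin (edgeR, adjusted p below 0.05). The median log2 fold change over all genes was -0.0047. The rest, named after their values were seen, were Klhl20, Exoc4, Arl6ip1, Enc1, Klhl33, Cd81 and LOC108349479, all higher, with log2 fold changes from 0.23 for Enc1 to 2.24 for Klhl33. The gene that fell, LOC103692829, was likewise named after its values were seen. It had 23 to 66 counts in each control library and 0 in every treated library, at least 59.4-fold lower when a floor of 3 counts is taken over the treated group. Control rats 1 and 5 had 61 and 66 counts, and control rats 4 and 9 had 23 and 25. A split described below that calls mostly copied genes divides the controls in the same way, though it did not call this gene. Counts of a gene without a name of its own are uncertain where near-identical copies share its reads. DESeq2 called 159 genes higher and 11 lower, including all 19. The edgeR count was 62 without doxorubicin rat 2, 11 without control rat 1 and without doxorubicin rat 6, 3 without control rat 9, 2 without control rat 4, and 1 without control rat 5 and without doxorubicin rat 8. Eda2r passed in each of these fits. With the set of rat numbers (1 to 4 or 5 to 9) as a block, chosen after seeing the data, 61 genes passed. Within rats 1 to 4 alone, edgeR called 0 genes (613 at an unadjusted p below 0.05, and 52 with DESeq2), and within rats 5 to 9 it called 92.

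Of the genes of the mitosis and G2/M list, 1 passed edgeR over all genes and 15 passed DESeq2, all higher. Prc1, which organises the central spindle, rose from 197.5 ± 8.89 to 236.1 ± 10.7 CPM, a log2 fold change of 0.26 ± 0.04 (edgeR adjusted p = 0.0446). Of the 74 measured members of the mitosis and G2/M list, 60 had a positive log2 fold change, with a median of 0.11. Adjusted over the list alone 33 passed edgeR, all higher, among them Aspm, Cenpf and Nusap1, which DESeq2 called over all genes, with log2 fold changes of 0.24, 0.18 and 0.28. The list rose in camera (adjusted p = 2.37e-18; adjusted p = 0.411 with an estimated correlation and 0.0536 with fry), and its mean had an exact permutation p of 0.0286 (0.223 adjusted over 39 lists). Top2a, the topoisomerase of dividing cells that doxorubicin targets, is a member and had a log2 fold change of 0.11 ± 0.04. It did not pass over all genes (edgeR adjusted p = 0.528) but was among those that passed when adjusted over the list alone. All its treated libraries lay above all control libraries (347.4 to 374.8 against 310.6 to 346.1 CPM). Top2b, its paralog outside the list, had a log2 fold change of -0.23 ± 0.16 (edgeR adjusted p over all genes = 0.874).

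In the list of DNA replication and G1/S genes, 52 of 58 members had a negative log2 fold change, with a median of -0.06 (camera adjusted p = 6.91e-07; adjusted p = 0.624 with an estimated correlation and 0.402 with fry). The list mean overlapped between the groups (exact permutation p = 0.114, or 0.446 adjusted over 39 lists). Control rat 1 had the highest mean log2 CPM (6.70), while control rat 9 (6.53) lay among the treated rats (6.52 to 6.56). Without control rat 1 the camera adjusted p was 0.0166. No member passed edgeR over all genes, where 1 was higher and 13 were lower at an unadjusted p below 0.05, and DESeq2 called 1 higher and 1 lower. Adjusted over the list alone, 1 member was higher and 1 lower. The higher one was Tyms, thymidylate synthase, at 133.0 ± 11.3 CPM in controls and 190.5 ± 20.9 CPM after doxorubicin, and the lower one was E2f8, a repressor of the E2F family, with a log2 fold change of -0.27 ± 0.06. The difference between the mitosis and the replication list means, computed after the 2 lists were seen to move apart and so no separate evidence, was 0.13 ± 0.05 log2 CPM in controls and 0.31 ± 0.02 after doxorubicin (SD, n = 4 each). Within rats 1 to 4 the medians of the mitosis and replication lists were 0.10 and -0.09, and within rats 5 to 9 they were 0.11 and -0.04.

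**Figure D2:**
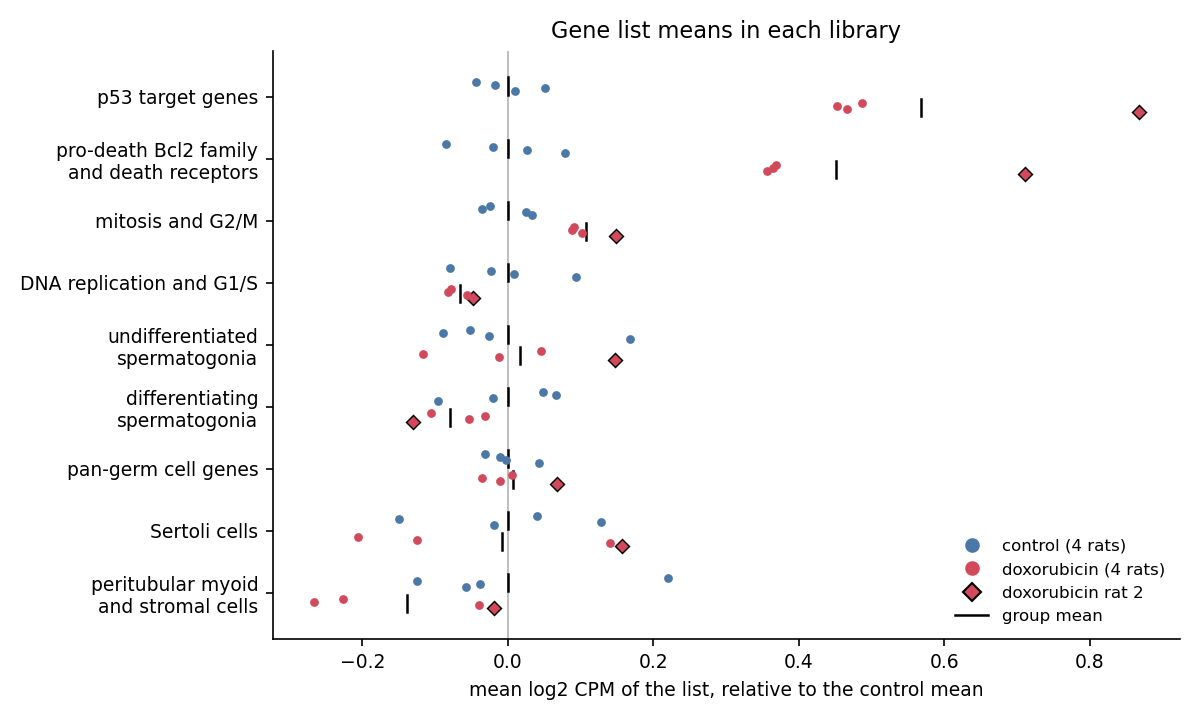
Mean log2 CPM of the genes of 9 lists in each library, relative to the mean of the 4 control libraries, with 1 point per rat (control in blue, doxorubicin in red) and a bar at each group mean. All treated libraries lie above all control libraries for p53 targets, the pro-death list and mitosis, while all other lists shown overlap between the groups.

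Lists of germ cell genes gave few calls. Of 31 measured pan-germ cell genes, 0 passed edgeR over all genes or adjusted over the list alone (1 at an unadjusted p below 0.05, and 0 with DESeq2), and camera gave adjusted p = 0.628. Ddx4, an RNA helicase of germ cells, stood at 377.1 ± 23.9 CPM in controls and 390.0 ± 5.64 CPM after doxorubicin, a log2 fold change of 0.05 with a 95% interval from -0.04 to 0.14. Dazl, a germ cell RNA-binding protein, had a log2 fold change of 0.06 (95% interval -0.01 to 0.13). Of the 42 genes of undifferentiated spermatogonia and stem cells, 0 passed (1 at an unadjusted p below 0.05, and 0 with DESeq2), with camera adjusted p = 0.749. The GDNF receptor Gfra1, the transcription factor Zbtb16 and the inhibitor Id4, all of this list, had log2 fold changes of 0.02 ± 0.05, -0.08 ± 0.05 and -0.04 ± 0.06. The differentiating spermatogonia list was lower in camera, with 17 of 20 members negative and a median of -0.07 (adjusted p = 0.036; adjusted p = 0.624 with an estimated correlation), though 0 members passed edgeR (2 lower at an unadjusted p below 0.05, and 0 with DESeq2). The list mean overlapped between the groups (exact permutation p = 0.114, or 0.446 adjusted over 39 lists). Its camera call was lost without control rat 4, 5 or 9 or doxorubicin rat 2 or 8, where adjusted p reached 0.156. Kit, the receptor that marks these cells, had a log2 fold change of -0.18 ± 0.12 (adjusted p = 0.86).

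Transcripts from lists of other testis cells were present at low levels, and which cells they came from was not tested. Few genes carried each sum: in the endothelial list Pecam1 alone stood at 70.7 ± 5.23 CPM in controls, and 4 of 12 members exceeded 10 CPM. In controls the summed abundance was 312.4 CPM for the Sertoli list, 197.8 CPM for peritubular myoid and stromal cells, 180.5 CPM for Leydig cells, 217.3 CPM for endothelial cells, 45.1 CPM for macrophages and leukocytes and 13.5 CPM for erythroid cells, against 4865 CPM for the pan-germ cell list. The peritubular and stromal list was lower after doxorubicin in camera, with a median log2 fold change of -0.21 (adjusted p = 0.036, but 0.624 with an estimated correlation). However, its summed abundance was 198.3 CPM in treated libraries. Its mean overlapped between the groups (exact permutation p = 0.257, or 0.501 adjusted over 39 lists). The camera call was lost without control rat 9 or doxorubicin rat 6 or 8, where adjusted p reached 0.31. Blocks chosen after seeing the data also lost it. There adjusted p was 0.0525 for the set of rat numbers and 0.0708 when a second split of the rats was added. The remaining 5 lists did not pass, with camera adjusted p of 0.811 for Sertoli, 0.216 for Leydig, 0.282 for macrophage and leukocyte, 0.77 for endothelial and 0.436 for erythroid genes.

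Library measures did not separate the groups. The share of counts from mitochondrially encoded genes was 8.13% ± 0.61 in controls and 8.14% ± 0.80 after doxorubicin (two-sided exact permutation p = 0.971, n = 4 each). The number of genes detected was 19796 ± 135 and 19798 ± 150 (exact permutation p = 0.914), the share of counts in the 50 highest genes was 0.10 percentage points higher after doxorubicin (exact permutation p = 0.857), and total counts were 51842300 ± 7359850 and 52813200 ± 7621830 (exact permutation p = 0.686). The first principal component held 26.5% of the variance and the second 17.5%, and neither separated the groups by an exact permutation test (p = 0.257 and 0.0571; 0.771 and 0.343 after Benjamini-Hochberg adjustment over these 6 measures).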

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

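Tests of depth and other cell types for rat 2, and the counts over other splits for the p53, mitosis and replication lists, for DESeq2, for named genes and for the number of lists, were set before their results were seen; the test of response size for rat 2, the tests of scaling, of rat 2 alone and of histone genes for mitosis and replication, the tests on the split of the animals that calls mostly copied genes (the copy-gene split), and the count of edgeR calls over other splits, were chosen after.

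Of 124 groups of 4 libraries examined, 13 had 1 library far from the rest, where chance gives about 1 in 20 groups, or 6.2, and 9 of them were doxorubicin rat 2. In that rat Aen stood at 125 CPM (83.3 to 88.6 in the other treated rats), Cd80 at 18.6, Cdkn1a at 36.0, Bax at 90.5, Pmaip1 at 83.9 and Btg2 at 38.7 CPM, all above the others. Zbtb16 stood at 88.2 CPM, below the others. The mean log2 CPM of the p53 target list was 4.57 and that of the pro-death list 3.74. The remaining values apart from their group were Ddx4 at 398 CPM in doxorubicin rat 8, and Gfra1 at 145, Tyms at 150 and Btg2 at 11.8 CPM in control rat 1.

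The 30 p53 targets that rose when adjusted over the list alone were higher in doxorubicin rat 2 than in the other treated rats by a median of 0.64 on the log2 scale, or 1.56-fold. After all libraries were thinned to the smallest total the excess was 0.61, which met the bound set in advance against sequencing depth. CPM values are already scaled to library totals, so thinning could hardly move the excess. The test therefore cannot decide whether library quality linked to depth plays a part. A larger response of the same genes in this rat predicts a positive slope of its excess on the fold change in the other treated rats. The slope was 0.31 (95% bootstrap interval 0.18 to 0.49), over 31 list genes that rose in the fit without that rat. The bootstrap resampled genes of 1 rat, which are correlated (0.26 estimated for the list), so its interval does not measure variation among rats. Other cell types cannot be told apart from a larger response. The largest excess among the 6 lists, 0.49 for Leydig genes, lies between the bounds set in advance. Doxorubicin rat 3, though, had a Leydig excess of 0.64 with p53 targets at -0.20. In mean log2 CPM the Leydig list of rat 2 (1.69) lay within the controls (1.49 to 1.79). Its excess reflects low values in doxorubicin rats 6 and 8 (0.95 and 0.86). The Sertoli, macrophage and leukocyte, and erythroid list means of rat 2 (1.77, 0.41 and 0.43) were above every control. Doxorubicin rat 3 was also above every control for Sertoli genes (1.75) and for macrophage and leukocyte genes (0.33). Doxorubicin rat 8 was so for macrophage and leukocyte genes only (0.25). Neither rat 3 nor rat 8 had an excess of p53 targets (-0.20 and -0.12). The most abundant Leydig list gene, Dlk1, measured 67.8 ± 5.58 CPM in controls and 4 of the 15 list genes exceeded 10 CPM there, and the isolation of GFP-positive cells selects against such cells.

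In camera with a preset correlation the mitosis list was higher and the DNA replication list lower after doxorubicin; with an estimated correlation adjusted p was 0.411 and 0.624, and the replication list mean alone had an exact permutation p of 0.114. Library scaling, which cannot move the difference between the 2 list means, is argued against because that difference had no overlap between the groups (exact permutation p = 0.0286). The 2 lists were picked after they were seen to move apart, so this p adds no evidence that both changed. Doxorubicin rat 2 alone is argued against too, since treated and control rats differed by 0.174 with and 0.166 without that rat. More cells in G2 and M and fewer in S phase may explain it as a hypothesis, but this stays open: the median log2 fold change of 29 replication-dependent histone genes was 0.0024 (95% bootstrap interval -0.16 to 0.04), and polyA libraries capture these transcripts poorly. Of the 35 splits of the 8 libraries, 1 gave the mitosis list a camera p as small, the real one (1.22e-19, against 5.85e-11 as the smallest of the others). For replication 4 did so, the real one included (5.31e-08, against 6.32e-11 as the smallest of the others), so chance cannot be excluded there. For mitosis, 1 of 35 is the smallest share that 4 against 4 rats can give. Its exact permutation p of 0.0286 for the list mean was 0.223 when adjusted over 39 lists (camera with an estimated correlation, adjusted p = 0.411, and fry, 0.0536). The count met the bound set before its result was seen, but cannot exclude chance for a list that stood out among 39.

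By the same count, 1 of the 35 splits gave the p53 target list a camera p as small, the real one (1.71e-23 against 6.07e-10 in the next). This too is the smallest share possible, with an exact permutation p of 0.0286 for the list mean, 0.223 when adjusted over 39 lists (camera with an estimated correlation, adjusted p = 0.411, and fry, 0.0536). The count met the bound set before its result was seen, but cannot exclude chance here either. Chance cannot be excluded for the count of genes, since 3 of the 35 splits, the real one included, called as many as the 19 found, the highest 42. The counts of splits that follow include the real one too. With DESeq2, 3 of 35 called as many as 170, the highest 633. Among genes with a name of their own it was 3 of 35 (17 against 26), and 8 of 35 splits called as many lists (9 against 11). The 633 came from rats 1 to 4 against rats 5 to 9, where edgeR called 28 genes. Control rat 1 and doxorubicin rats 2, 3 and 8 against the rest gave 596, a split that does not follow rat number. There edgeR called 1 gene over all genes and 19 when only genes with a name of their own were adjusted. Counts several times the real one point to a structure of the samples other than treatment. The 596 split follows the first principal component, negative in its named libraries (-34.0 to -1.56) and positive in the rest (7.02 to 21.9). That component comes from the same counts, so it names no cause. In the 633 and 596 splits the smallest libraries, control rat 9 (41253800 counts) and doxorubicin rat 6 (41665700), fell on the same side. Totals overlapped, since doxorubicin rat 3 (54933100) lay below doxorubicin rat 8 (55783100) or control rat 4 (55768700) on that side. Depth was not tested for these splits. The labels name no batch.

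The split with the most edgeR calls, 42, set control rats 1 and 5 and doxorubicin rats 3 and 6 against the others, a division defined from the data and not by the labels. Reads shared between near-identical copies may underlie it, since 90.5% of the called genes are pseudogenes, copies or rows without a name of their own, against 11.2% of genes tested (Fisher's exact test across genes, p = 3.55e-32). Sequencing depth is argued against by an exact permutation p of 0.657 for the totals of the 2 sets. Each set holds 2 treated and 2 control rats, so the design gives no biological explanation and none was tested. A strain variant or family structure among the rats was not tested, and the share of copies cannot tell either from shared reads.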

How the results depend on the processing

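Blocks for the rat numbers and the copy-gene split, the restriction to named genes, the newer quasi-likelihood method and robust limma-voom were chosen after seeing the data. The 19 edgeR calls became 170 with DESeq2, 53 without robust fitting, 61 with the rat-number set as a block, 97 with both splits as blocks, 4 with the newer quasi-likelihood method and robust dispersion, 30 with that method not robust, and 5 with robust limma-voom. They became 1 at an adjusted p below 0.01, 60 at 0.1 and 10 at an absolute log2 fold change of at least 1. Leaving out 1 library gave 1 (without control rat 5 or doxorubicin rat 8) to 62 genes (without doxorubicin rat 2). The cause was not tested, except that other thresholds change the count by construction. The other settings gave 16 to 24 genes. DESeq2, the fit that was not robust and the fit without doxorubicin rat 2 each kept all 19 genes. The 9 lists became 0 with an estimated correlation (2 at an unadjusted p below 0.05) and 0 with fry (5 at an unadjusted p below 0.05), and 6 to 11 with 1 library left out. Of the 6 lists of other cell types 1 passed, and 0 with an estimated correlation (0 at an unadjusted p below 0.05). Among 745 values for 44 named genes, 589 kept direction and side of the threshold, 44 newly passed, 110 no longer passed, and 2 reversed: Gfra1 at -0.0043 without doxorubicin rat 8 (range with 1 library left out -0.0043 to 0.0826) and Abcb1a at -0.0319 without control rat 4 (range -0.0319 to 0.384). Among 196 values for 14 lists, 154 kept both, 39 no longer passed, and 3 reversed, all for Sertoli cells, at adjusted p = 0.747, 0.822 and 0.478 without control rat 4, doxorubicin rat 6 and doxorubicin rat 8 (range 0.335 to 0.964 with 1 library left out); the cause was not tested.

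With 1 library left out, the difference in library measures, doxorubicin minus control, ran from -2558610 to 4686740 total counts, from -63.9 to 68.2 genes detected, from -0.245 to 0.346 percentage points in the 50 highest genes and from -0.356 to 0.263 in the mitochondrial share, so each changed sign. No paired analysis was possible because the 2 groups share no rat number. Gene length against fold change was not run, with gene span or exonic length or with library size only, for want of an annotation of the files' build. Depth limits genes near 1 CPM, where counting error alone reaches 15.6%.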

Other observations

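The tests described here use lists fixed before the data were examined; the choice of which to describe was made after. Cytosolic ribosomal protein genes were higher by a small amount in camera, with 61 of 72 members positive and a median log2 fold change of 0.03. Camera adjusted p was 6.44e-04, but 0.699 with an estimated correlation and 0.0564 without doxorubicin rat 6. The mean of this list overlapped between the groups (exact permutation p = 0.371, or 0.624 adjusted over 39 lists). Nuclear oxidative phosphorylation genes were lower in camera, 55 of 73 negative with a median of -0.03 (adjusted p = 0.0436, but 0.70 with an estimated correlation). Their list mean overlapped between the groups (exact permutation p = 0.743, or 0.955 adjusted over 39 lists). The camera call was lost without control rat 1, 4 or 5 or doxorubicin rat 3 or 8, where adjusted p reached 0.602. It was also lost with blocks chosen after seeing the data, at adjusted p = 0.0641 for the copy-gene split and 0.0609 for both splits. Immediate early genes were higher, 20 of 27 positive (camera adjusted p = 0.036; adjusted p = 0.624 with an estimated correlation), and lost the call without control rat 5 or doxorubicin rat 2 or 3, where adjusted p reached 0.335. In that list Jund and Btg2 passed when adjusted over the list alone, with log2 fold changes of 0.25 ± 0.05 and 0.91 ± 0.18. The list shares 1 member with the p53 targets. Its mean log2 CPM was 3.21 and 3.33 in doxorubicin rats 2 and 3, above the controls (2.88 to 3.06). In doxorubicin rats 6 and 8 it was 2.96 and 2.99, within them (exact permutation p = 0.229, or 0.495 adjusted over 39 lists).

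Several lists linked to DNA damage did not pass as sets. Camera adjusted p was 0.436 for DNA damage sensing and checkpoint genes, 0.289 for homologous recombination and Fanconi genes, 0.79 for non-homologous end joining and 0.669 for excision and mismatch repair. Meiosis genes had 29 of 40 members negative (adjusted p = 0.063). Among NF-kB and inflammatory mediators (adjusted p = 0.0764), 4 of 16 members passed when adjusted over the list alone, all higher, but 0 passed over all genes with edgeR (5 higher at an unadjusted p below 0.05) or with DESeq2. The list shares 2 members with the p53 targets, and its mean log2 CPM was 2.52 in doxorubicin rat 2, against 2.15 to 2.21 in the other treated rats. Drug transporters did not pass as a list (adjusted p = 0.289), with Abcb1b the 1 member of 13 that passed over all genes.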
